A study of Mus musculus with 16 samples.

How the data were processed

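RNA was sequenced in bulk from conventional type 1 dendritic cells (cDC1s), the dendritic cell type specialised in presenting antigen to CD8 T cells, which had been sorted by flow cytometry from mouse spleen at steady state. Per the labels, subsets of cDC1s at different stages of maturation were sorted straight into lysis buffer, RNA was purified with a column kit for small samples, and libraries followed a standard Illumina procedure. The 16 libraries form 4 groups of 4: immature and mature cDC1s from Xbp1fl mice, and immature and mature cDC1s from Xbp1flIre1fl mice. Xbp1 encodes a transcription factor of the unfolded protein response, and Ern1 encodes IRE1, the sensor that splices Xbp1 mRNA. Per the labels these genes carry loxP-flanked alleles in the mice but were not deleted, so both genotypes are described as functionally wild type. The sort gates are not given in the labels.

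The submitters' processing notes name FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.1.0, SAMtools 0.1.19 and limma 3.42.2, with the genome build mm10. The read counter, the gene annotation, the strandedness of the libraries and the handling of reads shared between related genes are not stated. The first deposited table holds raw counts per gene symbol, whole numbers for 24421 genes in each of the 16 libraries. The second deposited table holds log2 values for 11843 genes. Compared gene by gene with the raw counts, these log2 values equalled log2 CPM plus a constant per library, with a residual SD of at most 0.0298 over genes, and the authors do not state how they were normalized. The log2 table was used only as an alternative. Gene positions came from the GENCODE annotation of mm10, and for older symbols from RefSeq symbols and synonyms: 24326 of the 24421 symbols (99.6%) had 1 position and 95 had none.

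Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with too few counts for the 4 groups were removed with filterByExpr, which left 11978 genes, and libraries were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 16 libraries with robust estimation, with 12 residual degrees of freedom. Contrasts were tested with the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and changes over 2-fold were also counted. The contrasts were mature against immature as the mean of both genotypes, the same contrast within each genotype, the difference between these 2 (the interaction), and Xbp1flIre1fl against Xbp1fl within each stage. Levels are given as TMM-scaled CPM (counts per 1e6 counts), as mean and SD over libraries. Log2 fold changes are given with a standard error (SE) derived from the F-test, as the absolute log2 fold change divided by the square root of F. This SE is unreliable for large changes of genes with few counts in 1 stage. For Oprd1 it was 0.40 in Xbp1fl and 0.52 in Xbp1flIre1fl, but 1.33 for the interaction.

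There were 34 gene lists, fixed together with the contrasts, the tests and the rule for naming genes before the data were examined. Of these, 32 were tested with camera on log2 CPM (prior count 2) with its preset correlation of 0.01, with adjustment over the lists of a contrast. The other two, sex-linked genes and the floxed genes, served as checks. Some genes stand in more than 1 list. camera compares a list with all other genes. The same lists were tested with an estimated correlation between genes and with fry, whose p-value asks whether the genes of a list move, on balance, one way, and whose mixed p-value asks whether they change in either direction, without comparison with other genes. Genes were named by rule: the 6 with the largest change in each direction among called genes with at least 5 CPM in the higher stage, a symbol that is not a predicted or clone name, and no overlap between the stages, the 3 or 2 members of each list with the smallest adjusted p, the most abundant member of each list of other cell types, the 5 genes with the smallest adjusted p in each direction of the genotype contrasts, and 12 genes listed in advance, of which 2 are not reported here. Other list members and genes named as examples were chosen after their values were seen.

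Total counts per library ranged from 13948232 to 17000763, so that 3 counts, the floor used for a gene without counts, corresponded to 0.176 to 0.215 CPM. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. None of the 24 pairs of libraries within groups differed as little as sampling noise would give (chi-square per degree of freedom of 4.55 to 47.3), so none was counted as a duplicate. The labels do not say whether the libraries of a group came from separate mice, and p-values measure the spread between these libraries.

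The labels give each group replicate numbers 1 to 4. Over 8267 well expressed genes, deviations from the group means correlated in 8 of 8 pairs of mature and immature libraries of the same genotype and number (r of 0.248 to 0.505, across genes), each library correlated best with its own number, and the presence of Xist RNA matched in 8 of 8 pairs. Across genotypes 2 of 8 pairs of equal number passed a correlation of 0.1 (range -0.0860 to 0.333). The number was therefore read as a pairing within genotype only, and a fit with the replicate block was run as an alternative.

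In simulated data of the same size 200 genes were changed, and a further set of 20. Of the 200, the fit recovered 90% of 2-fold and 73% of 1.5-fold changes in the main contrast, 57% and 23% in the interaction, and 84% and 63% (immature) and 80% and 57% (mature) between genotypes. Within Xbp1fl it recovered 77% and 54%, and within Xbp1flIre1fl 81% and 62%. Between 2.35% and 7.98% of these calls were of unchanged genes. The simulated libraries were independent, with the same dispersion per gene in all groups. They left out the pairing and the wider spread of the mature Xbp1flIre1fl libraries. In the real data far more genes were called between stages, and fewer between genotypes or in the interaction. The recovered shares therefore do not give the power of the real contrasts.

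The alternatives were the replicate block, DESeq2 size factors in edgeR, upper quartile normalization, no low-count filter, a filter of 1 CPM in 4 samples, a fit without robust estimation, DESeq2 1.42.0, limma-voom, limma on the deposited log2 table, a fit to only the samples of the groups compared, a test against a 2-fold change (glmTreat), and leaving out each of the 16 libraries in turn. A further 3 were chosen after seeing the data: library sizes without normalization factors, leaving out the 2 mature Xbp1flIre1fl libraries with the lowest Ccr7 (numbers 2 and 4; also for the list tests between genotypes), and leaving out the 2 replicate numbers whose libraries contain Xist RNA (Xbp1fl 4 and Xbp1flIre1fl 3). For each contrast the samples were also split into other groups of equal size, in all 35 ways or in 100 ways drawn at random, and for the main contrast also in all 128 ways that part the 8 pairs. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the values reported, and no raw reads were used.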

Results

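Gene expression was measured by RNA sequencing in 16 libraries of splenic cDC1s: 4 of immature and 4 of homeostatic mature cells from Xbp1fl mice, and 4 of each from Xbp1flIre1fl mice. Mature libraries held 13948232 to 16572576 counts (n = 8) and immature libraries 15083053 to 17000763 (n = 8). Between 14116 and 14607 genes had a count in the mature libraries and between 13865 and 14295 in the immature ones. The first principal component held 71.0% of the variance and parted all mature from all immature libraries, and the next held 4.47% and 4.11%. TMM factors were 0.886 to 1.00 in mature and 1.06 to 1.12 in immature libraries. The 45S ribosomal RNA gene Rn45s took a median of 1.08% of the counts of mature libraries and 1.67% of those of immature libraries.

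The comparison of mature with immature cDC1s asks which genes change when these cells mature without infection, with the oxysterol-sensing LXR receptors named in the study's title. Ccr7, the chemokine receptor that guides dendritic cells to T cell zones (chromosome 11, 99144196 to 99155077), rose 53.2-fold, from 177 ± 72.3 to 9407 ± 2861 CPM (SD, n = 8 each; adjusted p = 1.0e-09). Abcg1, a cholesterol efflux transporter and LXR target (chromosome 17, 31057675 to 31117988), rose 4.86-fold, from 78.1 ± 3.17 to 380 ± 71.8 CPM (adjusted p = 1.7e-11). All 29 genes of a shared dendritic cell maturation programme rose, all 26 cell cycle genes fell, and most cholesterol synthesis genes rose. Changes reached 16-fold upward in 176 genes and downward in 0 of the genes called.

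The 6 largest rises by the naming rule were Zfp872, Oprd1, Scube3, Gcnt4, Pla2g4f and Gal3st2. Oprd1, the delta opioid receptor, was at 73.7 ± 21.4 CPM in mature and 0.177 ± 0.193 CPM in immature libraries (SD, n = 8; log2 fold change 9.17 ± 0.33, SE). That SE is unreliable at so low an immature level. The fitted log2 fold changes of the other five lay between 8.22 and 9.55, and rest on few immature counts: Zfp872 had 4 counts over all 8 immature libraries, Gcnt4 6, Scube3 and Gal3st2 7 each, and Pla2g4f 14. Their mature levels were 9.47 CPM (Gcnt4) to 30.5 CPM (Pla2g4f). The largest falls were smaller. Serpinb10 fell 4.89-fold, from 25.2 ± 4.01 to 5.14 ± 0.957 CPM, and Ccr2, a chemokine receptor best known from monocytes, fell 4.79-fold, from 90.5 ± 23.1 to 18.9 ± 5.09 CPM. Cd34, a progenitor marker, Atp8b4, Lmo1 and Anxa1 changed by -2.07, -1.53, -1.49 and -1.45 on the log2 scale. In each of these 12 genes all 8 mature libraries lay on the same side of all 8 immature libraries.

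Among the 29 tested genes of the shared maturation programme 29 rose (median log2 fold change 3.52). Fscn1, which bundles actin in dendritic processes, rose from 13.1 ± 5.48 to 2645 ± 629 CPM (SD, n = 8), Tmem123 changed by 4.37, Anxa3 by 6.24 and Serpinb6b by 1.70 on the log2 scale. The camera adjusted p was 5.8e-19, and adjusted p = 0.356 with an estimated correlation. Of 9 co-stimulatory ligands 7 rose, 1 fell and 1 did not pass (median 1.97; adjusted p = 0.0030, and adjusted p = 0.380 with an estimated correlation). Cd40 rose from 54.8 to 313 CPM (log2 fold change 2.52), Icosl changed by 2.84 and Cd83 by 0.98, while Cd86 changed by -0.15. Cd70 was at 5.56 CPM in mature libraries and had 9 counts over the 8 immature ones. Of 13 immunoregulatory genes 11 rose, 1 fell and 1 did not pass (median 3.25; adjusted p = 3.0e-05, and adjusted p = 0.275 with an estimated correlation). Among them were Socs2 (6.70), a suppressor of cytokine signalling, Aldh1a2 (3.56), which makes retinoic acid, and Cd274 (3.09), which encodes PD-L1, and Tgfb1 changed by -0.37. The NF-kB pathway list had 15 genes higher and 1 lower of 16 (median 1.80; adjusted p = 9.3e-08, and adjusted p = 0.380 with an estimated correlation). In it Relb and Birc2, of the non-canonical branch, changed by 3.31 and 2.61, and Nfkb1 by -0.47. For all of these lists the counts adjusted over the list alone were the same. Markers of B cells were also higher in the mature libraries (median log2 fold change 2.51).

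Of 18 tested LXR targets 11 rose, 2 fell and 5 did not pass, and 12 rose and 2 fell adjusted over the list alone (median log2 fold change 0.76). The risers included the efflux transporters Abcg1 (2.28 ± 0.10, SE) and Abca1 (1.68 ± 0.34), Arl4c (2.02 ± 0.11) and Apoe, which went from 112 ± 19.6 to 339 ± 37.8 CPM (SD, n = 8). Nr1h3, which encodes LXR alpha and is its own target, rose 2.23-fold (log2 fold change 1.16 ± 0.19, adjusted p = 3.9e-05). Of the lipogenic targets Scd1 changed by 1.77, while Fasn fell from 355 ± 13.2 to 213 ± 17.2 CPM, Scd2 changed by -0.58, and Srebf1 had a log2 fold change of -0.10 (adjusted p = 0.0917). The camera adjusted p of the list was 0.013, and adjusted p = 0.501 with an estimated correlation. Nr1h2, which encodes LXR beta, changed from 125 to 146 CPM (log2 fold change 0.23, adjusted p = 1.5e-04), and lost its call when libraries were scaled by total counts alone (0.01, adjusted p = 0.919). Macrophage markers, a cell type in which LXR targets are abundant, were higher in the same libraries (median 1.10).

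Of 23 tested genes of cholesterol synthesis and uptake 17 rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone (median log2 fold change 0.68). Idi1, an isomerase of the isoprenoid steps of cholesterol synthesis, rose from 60.4 ± 10.1 to 231 ± 63.2 CPM (SD, n = 8; log2 fold change 1.94 ± 0.17), and Sc5d, a sterol desaturase of a late step, changed by 1.13 ± 0.12. Ebp and Nsdhl, also of late steps, changed by -0.35 and -0.39. The adjusted p was 0.011, and adjusted p = 0.625 with an estimated correlation. With library sizes only 13 rose and 4 fell, and of the LXR targets 10 rose and 4 fell. Of 14 fatty acid synthesis genes 2 rose, 6 fell and 6 did not pass, also adjusted over the list alone, and the list was not called (adjusted p = 0.238). Its median was -0.14 and its mean 0.26, owing to Me1, which had 11 counts over the 8 immature libraries and 4.13 CPM in the mature ones.

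**Figure D1:**
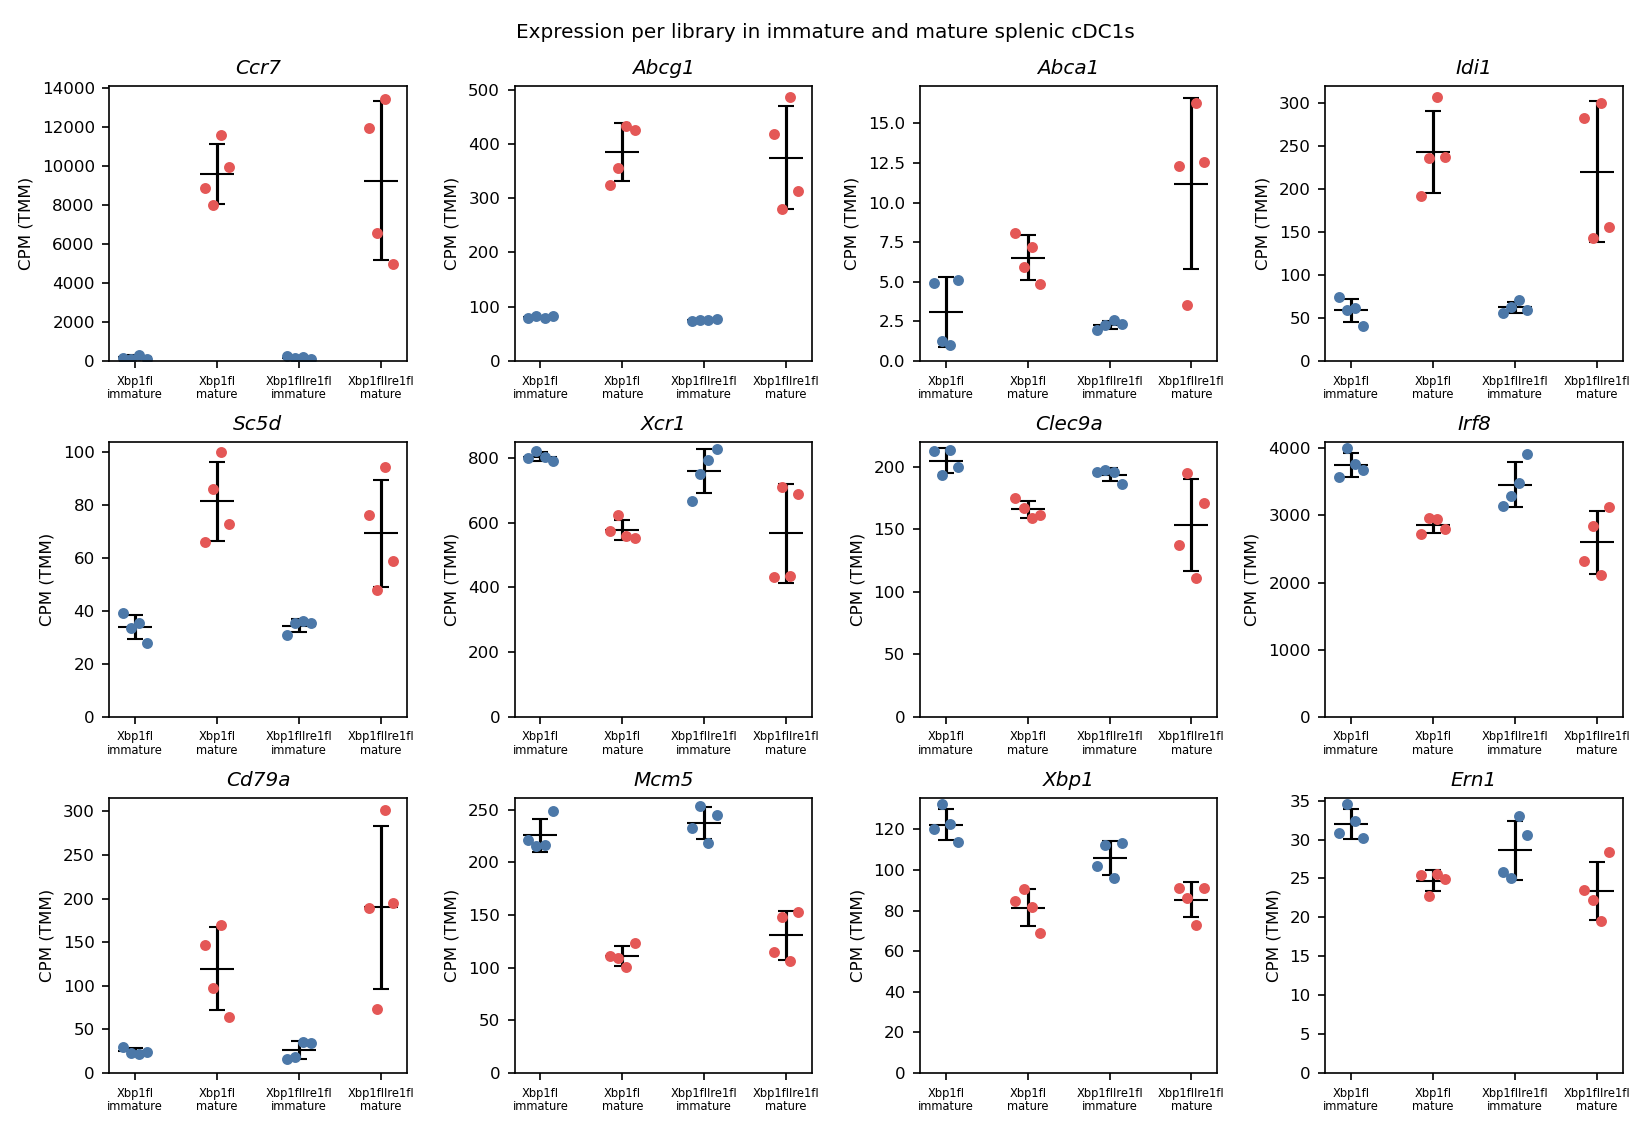
TMM-scaled CPM (counts per 1e6 counts) of 12 genes, 1 point per library, with the mean and SD of each group of 4 (black). Ccr7, Abcg1, Idi1, Sc5d and Cd79a were higher in all 8 mature libraries than in all 8 immature ones and Irf8, Mcm5 and Xbp1 lower, while the stages overlapped for Abca1, Xcr1, Clec9a and Ern1.

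Genes that define cDC1s went both ways. Of 19 identity genes 5 rose, 11 fell and 3 did not pass, also adjusted over the list alone (median log2 fold change -0.40; camera adjusted p = 0.182). Xcr1, the cDC1 chemokine receptor, fell 1.37-fold, from 782 ± 51.7 to 572 ± 102 CPM, Clec9a, a receptor for dead cells, changed by -0.32 ± 0.08 and the transcription factor gene Irf8 by -0.40 ± 0.07. Tlr3 changed by -1.03 and Rab7b by -0.70, while Ly75, which encodes DEC-205, and Id2 changed by 2.14 and 1.02. Of 16 tested receptors for apoptotic cells and antigen uptake 6 rose, 2 fell and 8 did not pass, also adjusted over the list alone (median 0.39; camera adjusted p = 0.182, fry adjusted p = 5.2e-06). Scarf1, Ly75 and Itgb5 changed by 3.53, 2.14 and 1.65. With library sizes only 5 rose and 5 fell. Of these receptors 3 were higher within Xbp1fl and 7 within Xbp1flIre1fl, and of 11 macrophage markers, higher in the same libraries (median 1.10), 3 and 9.

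Of 13 tested genes of MHC class I presentation 9 rose, 1 fell and 3 did not pass (median log2 fold change 0.55; adjusted p = 0.0046, and adjusted p = 0.392 with an estimated correlation). H2-K1 rose from 1537 to 4303 CPM, though reads can be shared with related class I genes, and Nlrc5, the class I transactivator, changed by 2.22. Of 11 genes of MHC class II presentation 4 rose, 6 fell and 1 did not pass (median -0.17; adjusted p = 0.447). Ciita, the class II transactivator, changed by -0.60 and H2-DMb1 by -0.67. Of 23 lysosomal genes 17 rose, 3 fell and 3 did not pass (median 0.51; adjusted p = 0.0011, and adjusted p = 0.275 with an estimated correlation), among them Lamp1 (2.61) and the protease gene Ctsz (1.09). Counts adjusted over the list alone were the same for these 3 lists. With library sizes only 7 class I genes rose and 4 fell, 1 class II gene rose and 7 fell, and 14 lysosomal genes rose and 6 fell. B cell and macrophage markers, from cells that also express class II genes, were higher in the same libraries (medians 2.51 and 1.10).

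Of 22 XBP1 targets and ER folding genes 5 rose, 14 fell and 3 did not pass, also adjusted over the list alone (median log2 fold change -0.37; adjusted p = 0.013, and adjusted p = 0.380 with an estimated correlation). The foldase genes Pdia6 and Pdia4 changed by -0.74 and -0.53 and Manf by -0.67, while Sel1l and Herpud1, of ER-associated degradation, changed by 0.77 and 0.69. The 26 cell cycle genes all fell, also adjusted over the list alone (median -0.84; adjusted p = 3.1e-10, and adjusted p = 0.380 with an estimated correlation). The replication factors Mcm5 and Mcm3 changed by -0.94 and -0.86 and the mitotic cyclin Ccnb2 by -1.28. Of 15 tested ATF4 and CHOP targets 5 rose and 5 fell (adjusted p = 0.845), with Ppp1r15a at 1.40 and the serine pathway gene Shmt2 at -0.77. Their median of 0.06 was -0.06 with upper quartile normalization and -0.17 with library sizes only. Respiratory chain genes had 2 higher, 17 lower and 3 not passing of 22 (median -0.27; adjusted p = 0.0030, and adjusted p = 0.541 with an estimated correlation), among them Atp5c1 (-0.40) and Uqcrc1 (-0.31). Of 14 glycolysis genes 2 rose, 6 fell and 6 did not pass (median -0.23; adjusted p = 0.151), with Aldoa at 0.69 and Tpi1 at -0.58, but 11 were lower with upper quartile normalization and 12 with library sizes only. Counts adjusted over the list alone were the same for these last 3 lists.

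Of 21 interferon-stimulated genes 13 rose, 3 fell and 5 did not pass, and 13 rose and 4 fell adjusted over the list alone (median log2 fold change 0.70; adjusted p = 0.026, and adjusted p = 0.541 with an estimated correlation). Oasl1, Rsad2 and Usp18 changed by 3.32, 1.97 and 1.82, and Irf7 by -0.47. Of 8 tested inflammatory cytokines 5 rose, 2 fell and 1 did not pass (median 0.97; adjusted p = 0.151). Il12b, a subunit of interleukin 12, rose from 71.3 ± 28.8 to 1808 ± 533 CPM, and Il27 and Il15 changed by 4.55 and 2.85. Of 20 chemokines and chemotactic receptors 10 rose, 5 fell and 5 did not pass (median 0.28; adjusted p = 0.162), including Ccl5 (5.81), Ccl22 (5.14) and Cxcl16 (2.54). Of 17 Toll-like receptors and nucleic acid sensors 7 rose, 8 fell and 2 did not pass (adjusted p = 0.961), with Tlr1 at 20.8 against 4.84 CPM and Ddx58 at a log2 fold change of 1.75. Their median of 0.11 was -0.01 with upper quartile normalization and -0.12 with library sizes only. The counts of the last 3 lists were the same adjusted over the list alone. Dissociation and immediate early genes had 4 higher and 4 lower of 14, and 4 higher and 3 lower adjusted over the list alone (median 0.00; adjusted p = 0.758). This median was -0.12 with upper quartile normalization and -0.22 with library sizes only. In this list Zfp36 and Junb changed by 0.83 and 0.67.

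Markers of other cell types were tested in the same libraries. All 10 tested B cell markers rose, also adjusted over the list alone (median log2 fold change 2.51; adjusted p = 3.7e-04, and adjusted p = 0.462 with an estimated correlation), with Ms4a1 at 171 ± 59.4 against 43.8 ± 7.85 CPM and Cd79a at 155 ± 78.1 against 25.5 ± 7.22 CPM (SD, n = 8). Of 11 macrophage markers 8 rose and 3 did not pass, also adjusted over the list alone (median 1.10; adjusted p = 0.027, and adjusted p = 0.625 with an estimated correlation). Without mature Xbp1flIre1fl replicate 4 this adjusted p was 0.0502. Vcam1 was at 348 against 80.5 CPM and Spic changed by 2.52. Of 9 tested cDC2 markers 5 rose and 4 did not pass, also adjusted over the list alone (median 0.92; adjusted p = 0.051, adjusted p = 0.435 with an estimated correlation, and 0.0297 with the replicate block). It was also called without Xbp1fl mature replicate 3 (adjusted p = 0.0264), without Xbp1fl immature replicate 1 (0.0407) or 2 (0.0373) and without Xbp1flIre1fl immature replicate 2 (0.0477) or 3 (0.050). Esam and Irf4 changed by 2.61 and 1.82, and Clec12a, the most abundant, had a log2 fold change of -0.03 (adjusted p = 0.586), but was called lower with upper quartile normalization (-0.15) and with library sizes only (-0.26).

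The other lists of foreign markers were not called by camera. For T cells 5 of 9 rose (median log2 fold change 0.78; adjusted p = 0.153), with Cd4 at 1.04. For plasma cells 2 of 3 rose (median 1.43; adjusted p = 0.225), and Jchain was at 222 ± 155 against 123 ± 47.7 CPM (adjusted p = 0.075). Jchain passed with a fit without robust estimation (0.0391), with DESeq2 (0.0373) and with mature Xbp1flIre1fl replicates 2 and 4 left out (0.0141), and without Xbp1fl mature replicate 3 (0.0430), Xbp1fl immature replicate 2 (0.0441) or Xbp1flIre1fl mature replicate 2 (0.0232). For plasmacytoid dendritic cells 2 rose and 1 fell of 7 (median -0.03, mean 0.36, camera upward at adjusted p = 0.793), with Ccr9 at -0.73. For NK cells 1 of 7 fell, Klrk1 (-1.01; median -0.03; adjusted p = 0.675). For neutrophils 1 of 7 fell, and 0 adjusted over the list alone (median -0.57; adjusted p = 0.225). Mpo had a log2 fold change of -1.79 ± 0.80 (adjusted p = 0.063), and passed with the replicate block (-1.77, adjusted p = 0.0081). Within Xbp1fl it was 0.06 ± 0.93 (adjusted p = 0.963) and within Xbp1flIre1fl -3.64 ± 1.28 (adjusted p = 0.0278), with an interaction adjusted p = 1.00. Its adjusted p was also under the threshold without Xbp1fl mature replicate 1 (0.0365) or 3 (0.0496), Xbp1fl immature replicate 3 (0.0349) or Xbp1flIre1fl immature replicate 3 (0.0449), and in 5 other alternatives (0.0327 to 0.0482). For stromal and endothelial cells 1 of 4 rose, Kdr (1.87), and the median of 0.08 (adjusted p = 0.809) was -0.04 with upper quartile normalization and -0.14 with library sizes only. For erythroid cells 0 of 2 passed (median 0.23; adjusted p = 0.934), with Alas2 at -0.15. For T cells, plasma cells, plasmacytoid dendritic cells, NK cells, stromal and erythroid cells the counts adjusted over the list alone were the same.

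**Figure D2:**
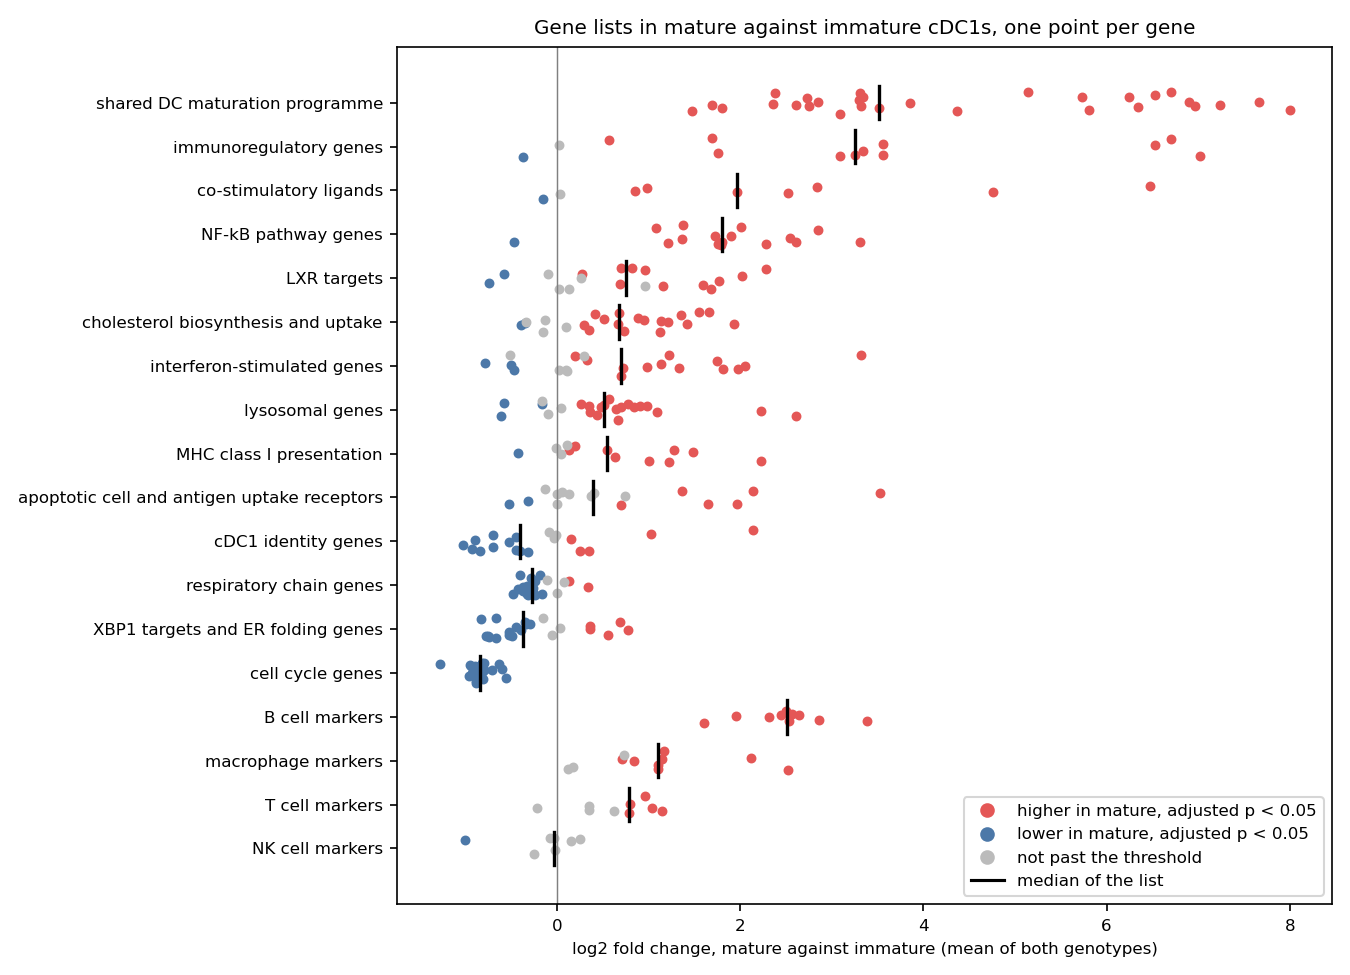
Log2 fold change of mature against immature cDC1s (mean of both genotypes) for each tested gene of 18 gene lists, coloured by the edgeR call, with the median of each list as a black line. All 29 maturation genes and 10 B cell markers lie right of 0 and all 26 cell cycle genes left of 0, and the medians of the lists shown kept their sign under the other scalings.

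By edgeR 8095 of 11978 genes (67.6%) were called between stages, 3995 higher and 4100 lower in mature cells, with 1473 higher and 174 lower by over 2-fold. The balance rests on the scaling: 3995 of 8095 calls were higher with TMM (median over all genes -0.01), 3213 of 8450 with upper quartile normalization (median -0.13) and 2716 of 8807 with library sizes only (median -0.23), and these scalings gave 28 and 416 of the called genes the opposite sign. The genes lower by over 2-fold numbered 337 with upper quartile normalization, 587 with library sizes only, 374 without the 2 mature Xbp1flIre1fl libraries of lowest Ccr7, and 21 when tested against a 2-fold change. Of 32 lists camera called 14, 11 upward and 3 downward, at adjusted p under 0.05 and 15 at unadjusted p. With an estimated correlation 0 were called and 3 had an unadjusted p under 0.05, while fry called 22 and its mixed test 28.

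Within Xbp1fl mice Ccr7 changed by 5.70 ± 0.44 (log2 fold change, SE), Abcg1 by 2.25 ± 0.14, Idi1 by 2.05 ± 0.25, Sc5d by 1.26 ± 0.18 and Nr1h3 by 0.96 ± 0.27, all called. Abca1, at 1.07 ± 0.47, did not pass (adjusted p = 0.0669). Of 18 LXR targets 9 rose and 2 fell, and of 23 cholesterol genes 16 rose and 2 fell, against 9 and 2 and 17 and 2 adjusted over the list alone. All 29 maturation genes rose and 25 of 26 cell cycle genes fell, against 29 and 26 adjusted over the list alone. By edgeR 6798 genes were called, 3407 higher and 3391 lower, and with library sizes only the lower ones numbered 5400. Macrophage markers had 3 of 11 higher, and all 10 B cell markers were higher, with the same counts adjusted over the list alone.

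Within Xbp1flIre1fl mice Ccr7 changed by 5.76 ± 0.44 (log2 fold change, SE), Abcg1 by 2.31 ± 0.14, Abca1 by 2.29 ± 0.48, Idi1 by 1.82 ± 0.24, Sc5d by 1.01 ± 0.18 and Nr1h3 by 1.36 ± 0.27, all called. Of 18 LXR targets 11 rose and 2 fell, and of 23 cholesterol genes 13 rose and 2 fell, against 12 and 2 and 14 and 2 adjusted over the list alone. All 29 maturation genes rose and all 26 cell cycle genes fell, also adjusted over the list alone. By edgeR 6406 genes were called, 3285 higher and 3121 lower, and with library sizes only the lower ones numbered 5104. Macrophage markers had 9 of 11 higher, and all 10 B cell markers were higher, with the same counts adjusted over the list alone. The mature libraries of this group spread most: Ccr7 was at 11921, 6574, 13425 and 4988 CPM in replicates 1 to 4, against 8001 to 11581 CPM in the mature Xbp1fl libraries.

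The maturation difference was compared between genotypes. Of the genes called, 5612 were called in both genotypes, 2880 higher in both and 2730 lower in both, where independent lists of these sizes would share 934 and 884. Both lists compare the same stages in a shared fit. An excess over independent lists was therefore foreseeable and does not measure how alike the genotypes are. The other 2 of the genes called in both had opposite directions. Of these Morn4, named after its values were seen, was higher in mature Xbp1fl cells (log2 fold change 1.02) and lower in mature Xbp1flIre1fl cells (-1.06). No gene, Morn4 included, was called in the interaction given below, so its reversal is not a called difference between genotypes. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r of 0.939 and Spearman rho of 0.900, with a slope of 0.921. A further 1186 genes were called in Xbp1fl alone and 794 in Xbp1flIre1fl alone.

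**Figure D3:**
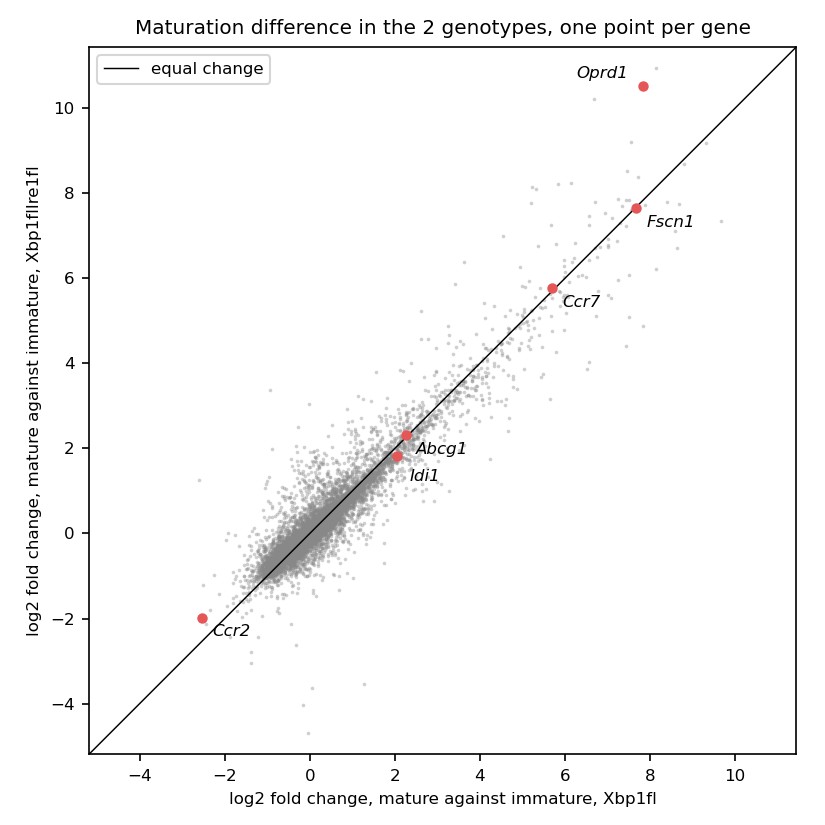
Log2 fold change of mature against immature cDC1s in Xbp1fl (horizontal axis) and Xbp1flIre1fl mice (vertical axis), 1 point per tested gene, with 6 genes named and a line of equal change. The points follow the line, with a Pearson r across genes of 0.939.

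The interaction asks whether the maturation difference itself differed between genotypes. No gene passed in edgeR: 0 of 11978 were called and 329 (2.75%) had an unadjusted p under 0.05. The fit with the replicate block, DESeq2, limma-voom and limma on the deposited log2 table also called 0. The difference was 0.06 ± 0.51 for Ccr7 (log2, SE), 0.05 ± 0.19 for Abcg1, -0.23 ± 0.34 for Idi1 and 1.22 ± 0.67 for Abca1, each at adjusted p = 1.00. camera called 8 lists, with B cell markers, macrophage markers, cell cycle genes and erythroid markers higher in Xbp1flIre1fl and cholesterol, maturation, NF-kB and dissociation genes lower, and 12 lists with the replicate block. Without mature Xbp1flIre1fl replicates 2 and 4, the libraries of lowest Ccr7, the maturation list turned upward (median 0.23 against -0.08, adjusted p = 0.0029), and the cholesterol (adjusted p = 0.693), cell cycle (0.867), NF-kB (0.107) and dissociation (0.0988) lists lost their calls. In that setting camera called 10 lists, 3 of the 8 in the same direction, 1 in the opposite direction and 6 others. With all libraries and an estimated correlation 0 were called (smallest adjusted p = 0.667, 0 at unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.779, 0 at unadjusted p under 0.05).

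The next comparison asks whether the genotypes, both described as functionally wild type, differed in immature cells. Of the 7 genes higher in immature Xbp1flIre1fl cells, Med1, a Mediator subunit (chromosome 11, 98152154 to 98193293), was at 118 ± 2.97 against 71.4 ± 6.64 CPM (SD, n = 4 each; adjusted p = 3.2e-05). Crnkl1 and Naa20, neighbours on chromosome 2 (145917479 to 145935014 and 145902099 to 145916425), were 1.98-fold and 2.03-fold higher. Lsm12 and Acbd4, on chromosome 11, had log2 fold changes of 0.48 and 1.07. Of the 9 lower genes, Arf2, a small GTPase gene (chromosome 11, 103966739 to 103985337), was at 29.5 ± 3.02 against 105 ± 16.3 CPM (adjusted p = 7.7e-07). Cyb561 (-1.70) and Pctp (-0.95), on chromosome 11, and Krtcap3 (-1.69), on chromosome 5, were also lower, as was Rps4l on chromosome 6 (-1.65), annotated as a processed pseudogene whose reads can be shared with related genes. By edgeR 16 genes were called (573 at unadjusted p under 0.05). DESeq2 called 40, the 16 among them. Without the replicate numbers containing Xist RNA 9 were called, all among the 16, with Acbd4 and Krtcap3 lost (adjusted p = 0.0721 and 0.0992), and without the 2 mature Xbp1flIre1fl libraries of lowest Ccr7 27 were called. camera called 3 lists, interferon-stimulated and cell cycle genes upward and erythroid markers downward, but 0 with an estimated correlation (smallest adjusted p = 0.794, 1 at unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.668, 1 at unadjusted p under 0.05).

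In mature cells 6 genes were higher and 11 lower in Xbp1flIre1fl, and 13 of these 17 were among the 16 of immature cells, all 13 in the same direction. The replicate numbers paired the stages within genotype, and both contrasts came from the same fit. This agreement is therefore not an independent replication. Arf2 was at 43.3 ± 6.48 against 192 ± 29.7 CPM (SD, n = 4 each; log2 fold change -2.15 ± 0.13, SE; adjusted p = 6.1e-08). Crnkl1, Naa20, Med1, Lsm12 and Acbd4 had log2 fold changes of 1.03, 0.99, 0.60, 0.44 and 1.15, and Rps4l, Cyb561, Krtcap3 and Pctp of -1.80, -1.96, -1.88 and -0.78. Of the 20 genes called in either stage, 13 lie on chromosome 11, which also holds Ern1 and Xbp1. By edgeR 754 genes had an unadjusted p under 0.05. DESeq2 called 36 genes, the 17 among them, 30 were called without mature Xbp1flIre1fl replicate 2, and 152 when replicate 4 was also left out. A fit to only the mature samples called 11, all among the 17, with Lsm12, Acbd4 and Pctp lost (adjusted p = 0.0964, 0.0529 and 0.0964). camera called 9 lists, with cell cycle genes, XBP1 targets, B cell and macrophage markers upward and cholesterol, maturation, cDC1 identity, dissociation and neutrophil genes downward, although the neutrophil median was 0.10. Without mature Xbp1flIre1fl replicates 2 and 4, the libraries of lowest Ccr7 (6574 and 4988 CPM), the maturation list turned upward (median 0.24 against -0.10, adjusted p = 4.1e-04), the cholesterol list (median 0.05 against -0.21, adjusted p = 0.536) and XBP1 targets (adjusted p = 0.391) lost their calls, and the cell cycle median was 0.13 against 0.29. In that setting camera called 15 lists, 6 of the 9 in the same direction, 1 in the opposite direction and 8 others. With all libraries and an estimated correlation 0 were called (smallest adjusted p = 0.663, 1 at unadjusted p under 0.05), and with fry 0 (smallest adjusted p = 0.546, 2 at unadjusted p under 0.05).

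**Figure D4:**
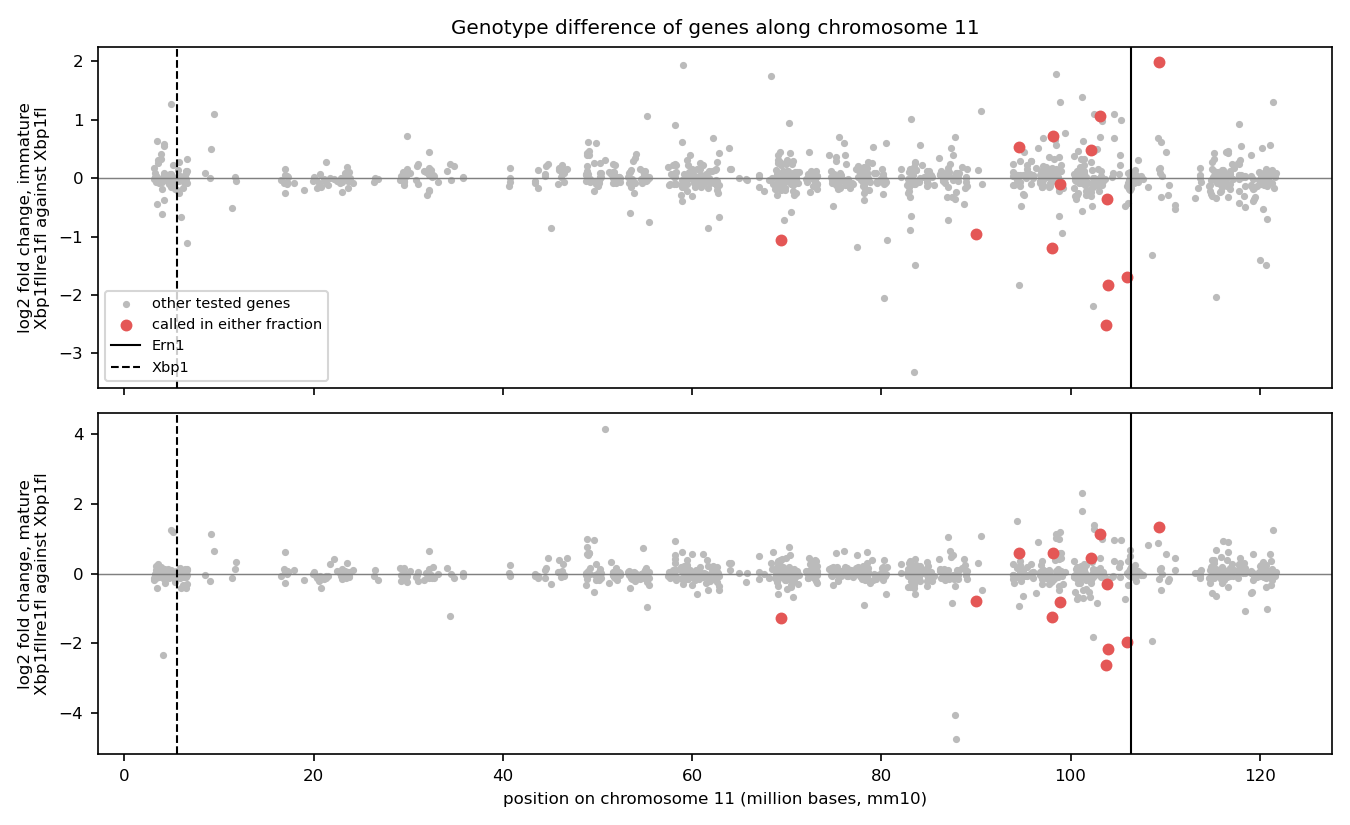
Log2 fold change of Xbp1flIre1fl against Xbp1fl in immature (top) and mature (bottom) cDC1s for tested genes along chromosome 11, in Mb of mm10, with the 13 genes called in either stage in red and lines at Ern1 and Xbp1. Of these 13 genes, 12 lie within 20 Mb of Ern1.

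The floxed genes themselves were measured in every library. Xbp1 (chromosome 11, 5520659 to 5525893) fell with maturation from 114 ± 11.5 to 83.4 ± 8.43 CPM (SD, n = 8; log2 fold change -0.45 ± 0.06, adjusted p = 6.3e-06). Ern1 (chromosome 11, 106394650 to 106487852) fell from 30.3 ± 3.33 to 24.1 ± 2.67 CPM (-0.33 ± 0.08, adjusted p = 9.5e-04). Both also fell adjusted over the list alone. Between genotypes the log2 difference of Xbp1 was -0.21 ± 0.09 in immature and 0.07 ± 0.09 in mature cells, and that of Ern1 -0.16 ± 0.11 and -0.08 ± 0.11 (adjusted p = 1.00, 0.964, 1.00 and 0.968). In immature cells Xbp1 was at 113.8 to 132.3 CPM in Xbp1fl and 96.1 to 113.3 CPM in Xbp1flIre1fl libraries, without overlap. Its interaction was 0.27 ± 0.13 (log2, SE) and not called. A small difference of Xbp1 between genotypes is therefore not excluded. The sign in mature cells turned for Xbp1 without Xbp1fl mature replicate 4 (-0.01), and for Ern1 without Xbp1flIre1fl mature replicate 3 (0.00020) and without the replicate numbers containing Xist RNA (0.00428). Of 5 sex-linked genes 0 passed between stages, also adjusted over the list alone. Their median of 0.12 was -0.00 with upper quartile normalization and -0.10 with library sizes only. Both stages of Xbp1fl replicate 4 and Xbp1flIre1fl replicate 3 contained Xist RNA and at most 0.108 CPM of the Y-linked Ddx3y. This widens the spread within groups, so the test could hardly find a difference between stages. In the other libraries Ddx3y was at 79.0 to 106 CPM in mature and 59.3 to 74.6 CPM in immature cells, without overlap, while the stages overlapped for Eif2s3y, Kdm5d and Uty.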

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

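Of the tests in this section, those of a lower cDC1 share, of scaling (for B cell markers and for Ccr7), of the excess of called genes near Ern1, and the comparison with the spread of the other mature libraries were chosen after the result was seen, and the second B cell list, the uncalled genes near Ern1 and the bound on the immature share were fixed before.

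B cell markers were higher in mature libraries, with a median log2 fold change of 2.51. B cell RNA or cells in the mature fraction would raise other B cell genes too. A second list, fixed before its values were seen, had a median of 1.00 (8 of 10 tested genes higher, Stap1 lower at -0.53, Fcrl1 at 0.06). This lies between the bounds set for and against. The bounds assumed an equal log2 rise, but added RNA raises a gene less on that scale where its immature level is higher. Immature levels in this list ran from 0.609 CPM (Vpreb3, log2 fold change 2.26) to 32.5 CPM (Stap1). The test therefore cannot decide, and the explanation stays open. A lower share of cDC1s in mature libraries was argued against only in the form that raises all foreign markers alike. The medians were -0.03 for NK cell markers (-0.25 to -0.02 over other settings), -0.03 for plasmacytoid dendritic cell markers and -0.57 for neutrophil markers, the last unsteady (-4.02 to -0.09). T cell (0.78), cDC2 (0.92), macrophage (1.10) and plasma cell (1.43) medians went the way a lower cDC1 share predicts. A larger share of some other cell types alone would leave the remaining lists unmoved, so the test cannot exclude it. Scaling was argued against as well, since 10 of 10 markers stayed called under 3 other scalings. Expression of these genes by mature cDC1s was not tested and could likewise account for the median of 1.00.

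Called genes between genotypes lie near Ern1: 12 of 20 within 20 Mb, against 418 of 11957 tested genes (3.50%; Fisher's exact p = 2.8e-13). This p restates the position that prompted the question, so an effect through the product of the altered allele stays open. Strain-derived sequence carried along with the altered allele would also shift uncalled neighbours: 19 of 406 uncalled genes in the window (4.68%) differed the same way in both stages, against 105 of 11531 elsewhere (0.911%), a Fisher odds ratio of 5.34 (95% interval 3.06 to 8.87), which is consistent with that hypothesis. Around Xbp1 the odds ratio was 0.842 (1 of 114 genes) and no gene was called. Both genotype labels include the floxed Xbp1 allele, so sequence carried along with it need not differ between them. The value around Xbp1 therefore does not show whether such sequence is present there.

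The mature Xbp1flIre1fl libraries spread widely, with replicates 2 and 4 lowest in Ccr7 and nearest to the immature libraries. Immature cells in the mature sort would give equal estimates of the immature share from rising and falling genes, but these were 0.451 and 0.184 in replicate 2 and 0.420 and 0.220 in replicate 4. The differences of 0.267 and 0.20 passed the bound against this explanation, yet lay near those of the other 6 mature libraries (-0.134 to 0.189, SD 0.135), and the explanation stays open. Scaling was argued against, because the Ccr7 share of all counts itself varied 2.40-fold among the 4 libraries.

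Splits of the samples into other groups bear on whether chance can be excluded. For mature against immature the real grouping gave 8095 called genes, and the highest other of the 128 splits that part all 8 pairs gave 6733, with 1 pair swapped, so chance was excluded (1 of 128 as large). These splits were run after 100 drawn without regard to pairs, whose highest other was 6680. Within a genotype the 8 splits that part all 4 pairs are too few for a share under 0.05: the real value was 6798 in Xbp1fl and 6406 in Xbp1flIre1fl, and the highest other 0 in both. The other splits of the 35, which leave pairs together, gave at most 1 and 428. For the genotypes in immature cells the real value was 16 and the highest other 0. This share of 1 of 35 is the smallest these splits allow and was not adjusted over the contrasts, so chance was not firmly excluded. For the genotypes in mature cells 3 of 35 splits gave as many (17, highest other 996), so chance was not excluded for this count. Nor was it for the interaction, where 13 of 35 gave as many genes at unadjusted p under 0.05 (329, highest other 1676), in fits without the replicate block. The split with 996 calls put Xbp1fl replicates 1 and 2 with Xbp1flIre1fl replicates 2 and 4. A split along another difference between libraries can give more calls, so these counts do not judge single genes.

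A library was listed as standing apart where its gap to the nearest library of its group of 4 was large relative to the range of the group, which about 1 in 20 groups would show by chance, and 20 of 400 groups did, of which 1 is left out here. Immature Xbp1fl replicate 3 was highest for Scube3 (0.0571 CPM), Gcnt4 (0.343 CPM), Gal3st2 (0.114 CPM), Anxa3 (3.77 CPM), Cd40 (59.2 CPM), Socs2 (4.11 CPM) and Relb (105 CPM). All of these genes rose with maturation. Ccr7, though not listed, was also highest in this library, at 320 CPM against 121 to 172 CPM in the rest of its group. Genes that change together are not independent, so the rate of 1 in 20 does not judge such a run. Immature Xbp1flIre1fl replicate 2 was highest for Pla2g4f (0.168 CPM), Me1 (0.112 CPM) and Uqcrc1 (293 CPM). Immature Xbp1flIre1fl replicate 3 was highest for Cd70 (0.115 CPM) and Rsad2 (8.46 CPM) and lowest for Il27 (0.115 CPM), and replicate 1 was lowest for Sc5d (30.8 CPM). For Scube3, Gcnt4, Gal3st2, Pla2g4f and Cd70 the other libraries of the group had no counts. Any count is then listed, and the rate of 1 in 20 does not hold for such groups. Immature Xbp1flIre1fl replicate 4 was highest for Birc2 (26.1 CPM) and in its TMM factor (1.12), and lowest for H2-DMb1 (551 CPM), Clec9a (186 CPM) and the percentage of counts in the 10 top genes (15.5%).

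In 8 lists camera called a difference in maturation between genotypes, given here as adjusted p and median log2 difference: cholesterol genes (0.0070; -0.19), the maturation programme (0.0456; -0.08), cell cycle genes (8.5e-05; 0.21), NF-kB genes (0.0388; -0.17), dissociation genes (0.0388; -0.15), B cell markers (0.0063; 0.67), macrophage markers (0.0063; 1.10) and erythroid markers (0.0394; 1.57). With an estimated correlation the adjusted p was 0.764 for the maturation programme and 0.667 for the smallest of all lists. Without the 2 mature Xbp1flIre1fl libraries of lowest Ccr7, 3 of the 8 lists kept their call (B cell, macrophage and erythroid markers) and the maturation programme turned.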

How the results depend on the processing

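Of the 8095 genes called in the mean stage contrast, 6841 (library sizes only) to 8080 (not robust) were also called in the alternatives that tested any difference, while the balance of directions followed the scaling and the genotype calls were few. A test against a 2-fold change, a narrower question, called 1020 higher and 21 lower. Of 104 named gene results 94 kept the same call in the alternatives run for them. The fit to only the samples compared covered 20 of these results, and glmTreat none. The cause of the changes was not tested. The mean stage contrast had 8347 called genes with the replicate block, 8165 with DESeq2, 8127 with limma-voom, 8450 without the 2 mature Xbp1flIre1fl libraries of lowest Ccr7 and 7212 without the replicate numbers containing Xist RNA. Across genotypes the numbers are no pairing, and a fit with that block called 22 genes in immature and 21 in mature cells.

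Against 174 genes lower by over 2-fold there were 337 with upper quartile normalization, 587 with library sizes only, 374 without the 2 libraries of lowest Ccr7 and 21 with glmTreat. With library sizes only 5400 genes were lower within Xbp1fl and 5104 within Xbp1flIre1fl. DESeq2 called 40 genes between genotypes in immature cells (17 higher, 23 lower) and 36 in mature cells (17 and 19). A fit to only the samples compared gave 11 higher in immature cells, and 11 in mature cells, 3 of them higher. Without the 2 libraries of lowest Ccr7 it was 27 (11 and 16) and 152 (51 and 101), a choice made on an outcome and so no test of genotype. Without the Xist numbers it was 9 (4 and 5), and 11 higher in mature cells. Without mature Xbp1flIre1fl replicate 2 it was 30 in mature cells, 17 higher. Of 14 lists called, 0 were called with an estimated correlation, and fry called 22. The correlation between genotypes was 0.911 without immature Xbp1flIre1fl replicate 4.

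Signs turned for Alas2 (0.0879, without the 2 libraries of lowest Ccr7), for Xbp1 between genotypes in mature cells (-0.00586, without mature Xbp1fl replicate 4) and for Ern1 (0.000199 without mature Xbp1flIre1fl replicate 3, 0.00428 without the Xist numbers). The direction of the list of Toll-like receptors turned in 2 settings (adjusted p 0.855 and 0.960; range over left-out libraries 0.823 to 0.991) and that of erythroid markers in 4 (0.979, 0.954, 0.979 and 0.994; range 0.810 to 0.994), none called. Between genotypes in mature cells Xbp1 ranged up to 0.135 and Ern1 down to -0.183 over left-out libraries.

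Leaving out each library in turn gave 7765 to 8263 called genes (3823 to 4084 higher, 3942 to 4182 lower; over 2-fold 1412 to 1571 and 145 to 243), 6230 to 6966 within Xbp1fl, 5496 to 6674 within Xbp1flIre1fl, 0 for the interaction, 11 to 21 between genotypes in immature and 15 to 30 in mature cells, 13 to 15 lists, and a correlation between genotypes of 0.911 to 0.933.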

Other observations

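Further members of the lists above, chosen after their values were seen, are given here and were already counted there. B cell and macrophage markers were also higher in the mature libraries. S1pr1, a receptor for the egress signal sphingosine 1-phosphate, rose with maturation (log2 fold change 2.60), as did Cd63 (6.90), a tetraspanin of late endosomes, and Lgmn (2.23), a lysosomal protease, while Cd68 changed by -0.61. Slc7a11, the cystine transporter, changed by 2.86, whereas Asns, Psat1 and Phgdh, of amino acid synthesis, changed by -0.93, -0.91 and -0.87.

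The genotype calls near Ern1 may be of use to anyone comparing these lines, since the odds ratio of 5.34 for uncalled neighbours is consistent with flanking sequence from another strain as a hypothesis. Variants in the raw reads around Ern1 would test it.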
